A study of Homo sapiens with 8 samples.

How the data were processed

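RNA was sequenced from A549 cells in 8 libraries, 2 for each of 4 groups: scr and CSE knockdown, each non-senescent and senescent. Per the labels, senescence was induced with 7 Gy of ionizing radiation and cells were harvested 72 hours later. The knockdown target CSE was read as cystathionine gamma-lyase (gene symbol CTH). The deposited table holds 1 whole-number count per gene and library, so its unit is the raw count. Per the submitters' processing notes, fastp, FastQC, MultiQC and featureCounts and the builds GRCh38.p13 and hg38 were used, without versions. The aligner is not given in the sources used here, nor is the strandedness of counting.

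The table was checked before use. Per the file headers, a length is listed for each gene, and for the 57947 genes with 1 location it equals the whole span, introns included. Nested gene pairs on opposite strands were checked where the inner gene had at least 100 counts in total. In 3802 of 3802 such pairs the outer gene had at least the count of the inner gene in every library. The same held in 2397 of 2397 nested pairs on the same strand. Reads counted without strand and for each gene they overlap would give this. Even counts were in excess (61.4% of counts above 0; 7980 counts of exactly 1 against 25756 of exactly 2), so counts divided by 2 were tried as an alternative. Gene names came from a table of identifiers and from GENCODE 29. Mitochondrial transcripts took 5.88% to 7.72% of counts.

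Depth was 92654974 and 84313805 counts in scr non-senescent, 77940297 and 72769287 in scr senescent, 103058790 and 96285849 in knockdown non-senescent and 70838078 and 88757068 in knockdown senescent libraries. A count of 0 allows up to 3 counts at the 95% level, 0.0300 to 0.0403 CPM. For a gene with no counts in a group, the fold was computed against 3 counts over the group, and for 1 to 3 counts a ratio with its exact counting interval was given. CPM used TMM-scaled library sizes.

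Genes were tested with edgeR 4.0.16 in R 4.3.3. After filterByExpr, 29955 genes were kept, scaled with TMM and fitted by quasi-likelihood with robust moderation and 1 coefficient per group (4 residual degrees of freedom, median prior degrees of freedom 21.7, common dispersion 0.0141). The 5 comparisons were irradiation in scr and in knockdown cells, knockdown in non-senescent and in senescent cells, and their interaction. The 2 knockdown comparisons share no library, nor do the 2 irradiation comparisons. P-values were adjusted by Benjamini-Hochberg at 0.05. A set of 31 gene lists was tested with camera (limma 3.58.1, preset correlation 0.01), with camera with an estimated correlation and with fry. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

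Groups, comparisons, gene lists, the rule for named genes and most alternatives were set before the data were examined. The rule covers 11 genes in every comparison, not all of them discussed in each (CTH, CSE1L, CBS, MPST, CDKN1A, MDM2, LMNB1, MKI67, IL6, CXCL8 and GLB1), the 6 largest rises and 6 largest falls among called genes with an average log2 CPM of at least 0 and no overlap between the groups, and up to 3 members of up to 8 called lists. Y-linked genes were left out, as were results on a few genes withheld for evaluation.

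Alternatives set beforehand were RLE size factors, no filter, a filter at 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, only the libraries of a comparison, a block for either number in the sample titles, a minimum fold of 2, and leaving out each library. Chosen after seeing the data were library size without TMM, a correction for GC content and gene span, genes overlapping no other gene, and counts divided by 2. The correction fitted loess curves (span 0.5) to each library over 13156 genes and entered the edgeR fit as offsets. Windows of 20 Mb with at least 15 protein-coding genes were used for position.

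The procedure was tested on simulated data with 200 changed genes per comparison. Of genes changed 2-fold, 86%, 68%, 74%, 80% and 78% were recovered in the 5 comparisons, and 8 to 14 other genes were called. Of those changed 1.2-fold, 0% to 6% were recovered. The changed genes were drawn only from genes above a minimum expected count, so recovery of genes with fewer counts was not tested. No GC trend was added in these simulations, so the 8 to 14 other calls do not measure false calls in the deposited data. A list raised 1.5-fold was called by camera, by camera with an estimated correlation (adjusted p = 0.000536) and by fry, with 0 of 30 other lists called. Each gene was drawn independently there, so this does not show how often camera calls lists whose members vary together. Simulated windows raised 1.5-fold had medians of 0.54 and 0.57, and the highest other window 0.07. With a GC trend of rho = -0.87 added, 3847 other genes were called without and 11 with the correction, which recovered 152 of 200 changed genes against 169 without it.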

Results

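A549 cells, a human lung epithelial cancer line, carried either a scr control or a CSE knockdown and were compared as non-senescent cells and as cells made senescent with 7 Gy of ionizing radiation and harvested 72 hours later. Each of the 4 groups had 2 libraries, 8 in all, with 70838078 to 103058790 counts per library over 57992 genes. Of these, 29955 genes had enough counts to be tested. A count of 0 allows up to 3 counts at the 95% level, which was 0.0300 to 0.0403 CPM in a library. These intervals and floors cover counting error only and take each count as 1 event; since even counts are in excess, values are also given for counts divided by 2, as when both mates of a read pair are counted. No source says whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries. Nor do the sources used here say whether the knockdown was stable or transient. Where the text speaks of scr and knockdown lines, separate lines are an assumption.

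Libraries lay closest to their own group. The first principal component held 50.8% of the variance and the second 23.4%. Across genes, which are not independent replicates, log2 CPM correlated at 0.982 to 0.986 within groups and at 0.925 to 0.973 between libraries of different groups. Libraries also differed by the GC content of genes. In scr non-senescent replicate 1 the median log2 deviation from the gene mean went from -0.34 in the lowest to 0.50 in the highest of 5 equal bins of genes by GC, while in CSE knockdown senescent replicate 2 it went from 0.22 to -0.24.

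**Figure D1:**
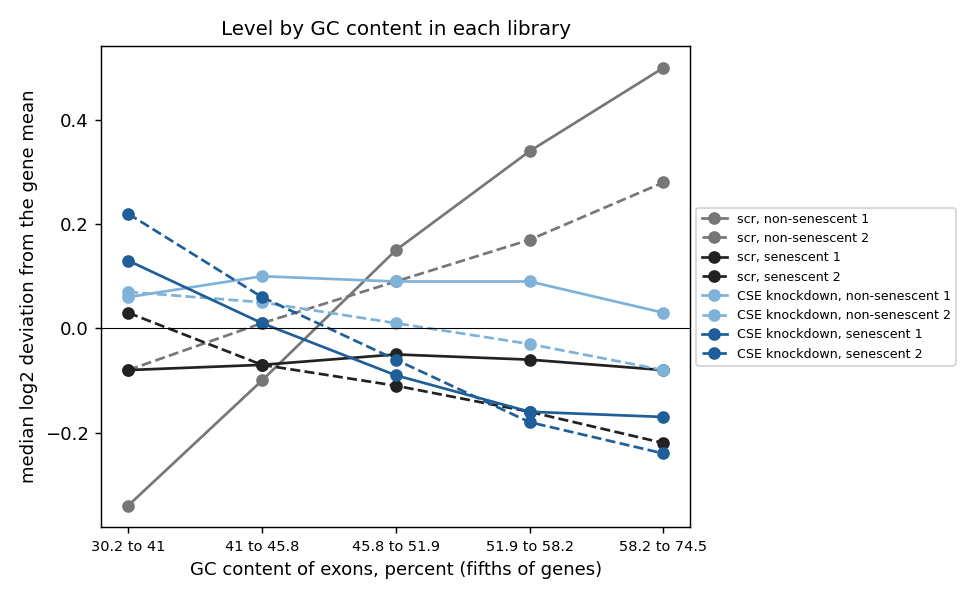
Median log2 deviation from the gene mean (vertical axis) in 5 equal bins of protein-coding genes by exon GC percent (horizontal axis), with 1 line for each of the 8 libraries. The lines of the 2 scr non-senescent libraries climb to 0.50 and 0.28, and those of the 2 senescent knockdown libraries descend.

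CTH, the gene of cystathionine gamma-lyase (chromosome 1, 70411218 to 70439851, GRCh38; ENSG00000116761.11) and the usual reading of CSE, was lower in the knockdown libraries. Its level was 1.66 and 0.964 CPM in scr non-senescent, 2.41 and 1.44 in scr senescent, 0.462 and 0.850 in knockdown non-senescent and 0.537 and 0.449 in knockdown senescent libraries. These levels rest on 133 and 75, 196 and 115, 46 and 85, and 40 and 41 counts. By edgeR with Benjamini-Hochberg adjustment, CTH fell by 1.0 on the log2 scale in non-senescent cells (SE 0.37, adjusted p = 0.0378) and by 1.96 in senescent cells (SE 0.38, adjusted p = 0.000278). The non-senescent call ended in DESeq2 (-1.02, adjusted p = 0.0562), with library size alone (-0.81, adjusted p = 0.135), with a block for the number in the sample titles (-0.68, adjusted p = 0.206), without scr non-senescent replicate 1 (-0.52, adjusted p = 0.454) and without knockdown non-senescent replicate 1 (-0.67, adjusted p = 0.255), while without knockdown non-senescent replicate 2 the fall was larger (-1.54, adjusted p = 0.00929). CSE1L, the nuclear export factor gene that shares the abbreviation (chromosome 20; ENSG00000124207.16), did not pass in non-senescent knockdown cells (0.05, SE 0.11, adjusted p = 0.767; -0.21, adjusted p = 0.0205 after a GC correction). In senescent knockdown cells CSE1L rose by 0.38 (SE 0.11, adjusted p = 0.00864), a call that ended without scr senescent replicate 2 (adjusted p = 0.0657) or knockdown senescent replicate 2 (0.25, adjusted p = 0.241).

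**Figure D2:**
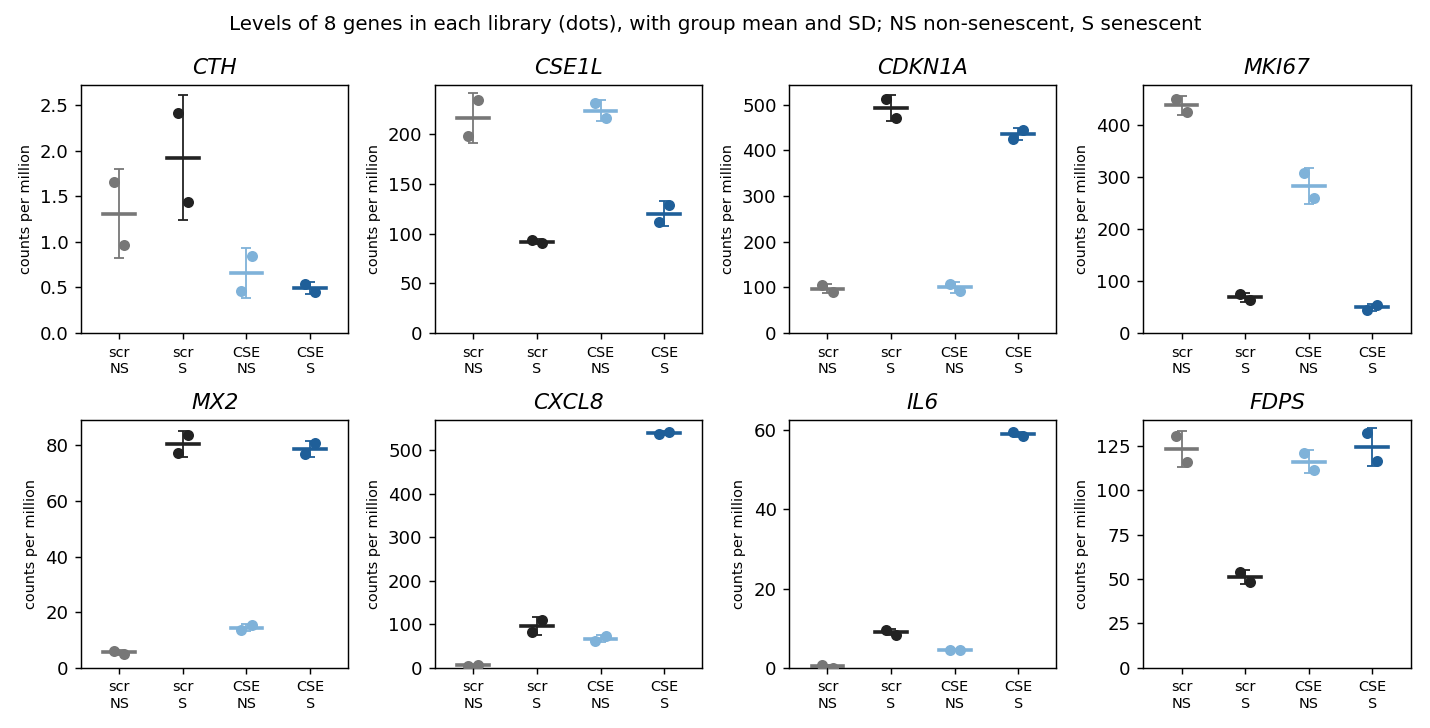
CPM of 8 genes (vertical axes, each from 0) in the 4 groups (horizontal axes), with each library as a dot, the group mean as a bar and the SD as whiskers. CTH lies at 0.449 to 0.850 CPM in the 4 knockdown libraries and at 0.964 to 2.41 CPM in the 4 scr libraries.

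After irradiation, scr cells had fewer transcripts of cell division genes and more of interferon-stimulated, antigen presentation and secretory genes (log2 fold changes, n = 2 libraries per group). All 36 genes of G2/M and mitosis fell (median -2.21), among them the mitotic kinase gene PLK1 (-3.05, SE 0.12) and CDC20 (-2.96, SE 0.13), whose product activates the anaphase-promoting complex. All 41 genes of DNA replication and E2F targets fell (median -1.86), with E2F1, a driver of entry into S phase, at -2.67 (SE 0.12). All 39 interferon-stimulated genes rose (median 2.56), with IFIT2 at 6.05 (SE 0.14), and all 15 genes of MHC class I antigen presentation rose (median 2.30), with HLA-B at 4.19 (SE 0.13). Of 45 senescence-associated secretory factor genes, 35 rose, 4 fell and 6 did not pass (median 1.57). The cytokine genes IL6 (4.76, SE 0.47; 7.42 without scr non-senescent replicate 1) and CXCL8 (4.02, SE 0.16) and INHBA, which encodes the activin A subunit (6.46, SE 0.23), were among those that rose.

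In the same comparison, 29 of 36 p53 target genes rose and 1 fell (median 0.66), with the cell cycle inhibitor gene CDKN1A at 2.34 (SE 0.11) and MDM2, which encodes the ligase that degrades p53, at 2.45 (SE 0.12). Of the 18 NF-kB feedback and target genes, 17 rose (median 1.46), with TNFAIP3, an inhibitor of that pathway, at 3.93 (SE 0.12). Of 20 homologous recombination and crosslink repair genes, 18 fell (median -1.58), and of 14 nuclear senescence hallmark genes, 13 fell (median -1.57), including the lamin gene LMNB1 (-2.19, SE 0.11). For these 9 lists the counts were the same adjusted over the list alone, and camera called each of them (adjusted p from 3.53e-99 to 1.22e-15; adjusted p from 0.019 to 0.0457 with an estimated correlation). GLB1, the lysosomal beta-galactosidase gene, rose by 0.25 (SE 0.10, adjusted p = 0.0466). That call ended without scr non-senescent replicate 2 (adjusted p = 0.172), without scr senescent replicate 1 (adjusted p = 0.32) without knockdown senescent replicate 1 or 2 (adjusted p = 0.0525 and 0.0519) without a filter (adjusted p = 0.0602), with only the libraries of the comparison (adjusted p = 0.0765) and with a block for the number in the sample titles (0.18, adjusted p = 0.129).

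Ribosomal and respiratory genes fell as well in irradiated scr cells: 57 of 58 cytosolic ribosomal protein genes (58 adjusted over the list alone; median -0.78) and 40 of 44 nuclear-encoded respiratory chain genes (41 adjusted over the list alone; median -0.74). Camera called both, with adjusted p = 0.347 and 0.285 with an estimated correlation, and after the GC correction their medians were -0.41 and -0.48. Of 25 cholesterol biosynthesis genes, 15 fell and 5 rose (15 and 6 adjusted over the list alone; median -0.49; adjusted p = 0.355 with an estimated correlation), and that call ended after the GC correction (median -0.11, adjusted p = 0.112). Of 12 alveolar type 2 markers, 3 rose and 1 fell, also adjusted over the list alone (median 1.38, adjusted p = 0.0302; adjusted p = 0.18 with an estimated correlation). Leaving out scr non-senescent replicate 2 (median 2.09, adjusted p = 0.0509), scr senescent replicate 1 (0.1) or 2 (median 0.81, adjusted p = 0.144) or knockdown non-senescent replicate 1 or 2 (0.103 and 0.128) ended the alveolar call.

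The largest single rises after irradiation in scr cells were in genes near the floor beforehand. SAA2, an acute-phase protein gene, went from 0 to 438 counts over the group, at least 143-fold higher against a floor of 3 counts over the group (at least 71.5-fold with counts divided by 2), and CSF3, the gene of granulocyte colony-stimulating factor, from 1 to 212 counts (ratio 208, 95% counting interval 36.9 to 8240, or 18.2 to 4140 with counts divided by 2). In the second interval the lone count of 1 was kept at 1, so only the larger count was divided. CXCL11 (8.32, SE 0.32) and IDO1 (8.03, SE 0.22) also rose, while the telomerase gene TERT fell by 3.08 (SE 0.15). SAA2, CXCL11, IDO1 and IFIT2 overlap other genes, and reads shared between overlapping genes leave their own share uncertain. Over all tested genes, 15320 changed by edgeR with Benjamini-Hochberg adjustment at 0.05, 7742 higher and 7578 lower, and 7024 of them by at least 2-fold (4668 higher, 2356 lower). The share higher was 50.5%, 66.6% with library size alone and 61.5% after the GC correction. Library size alone moved the median log2 fold change of all genes by 0.26 in this comparison, by 0.16 in the non-senescent knockdown comparison and by -0.21 in the interaction.

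In CSE knockdown cells irradiation moved largely the same groups. All 36 G2/M and mitosis genes (median -2.16) and all 41 replication genes (median -1.56) fell, with the kinesin gene KIF20A at -2.85 (SE 0.13) and MCM10, a replication initiation gene, at -2.21 (SE 0.12). Of the 39 interferon-stimulated genes, 38 rose (median 2.13), with IFIT2 at 4.73 (SE 0.13), and all 15 MHC class I genes rose (median 1.76), with HLA-B at 3.35 (SE 0.13). Of the 45 secretory factor genes, 36 rose and 2 fell (36 and 3 adjusted over the list alone; median 1.27). IL6 rose from 4.42 to 58.9 CPM (3.74, SE 0.34) and CXCL8 from 66.7 to 540 CPM (3.02, SE 0.15). Of the p53 targets 30 rose and 1 fell (31 and 1 adjusted over the list alone; median 0.76), with CDKN1A at 2.12 (SE 0.11) and MDM2 at 2.06 (SE 0.12), and 14 of 18 NF-kB genes rose (15 adjusted over the list alone; median 1.05). All 14 nuclear hallmark genes (median -1.45) and 19 of 20 recombination genes (20 adjusted over the list alone; median -1.38) fell.

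Unlike in scr cells, the cholesterol biosynthesis list was higher after irradiation in knockdown cells: 12 of 25 genes rose and 5 fell (14 and 5 adjusted over the list alone; median 0.30; adjusted p = 0.418 with an estimated correlation). CBS, which encodes the first enzyme of transsulfuration, fell by 0.42 (SE 0.13, adjusted p = 0.0111), a call that ended without knockdown non-senescent replicate 1 (adjusted p = 0.222), without knockdown senescent replicate 1 or 2 (0.0792 and 0.137) and after the GC correction (-0.18, adjusted p = 0.121). In scr cells CBS did not pass (-0.01, adjusted p = 0.977) but was at 0.51 (adjusted p = 5.65e-05) after the GC correction. The difference between the lines for CBS did not pass either (-0.41, SE 0.18, adjusted p = 0.121), but did without scr non-senescent replicate 1 (-0.61, adjusted p = 0.0213), with library size alone (-0.62, adjusted p = 0.0184), with a block for the replicate number (-0.41, adjusted p = 0.0441), with a filter at 1 CPM in 4 libraries (-0.51, adjusted p = 0.0353) and after the GC correction (-0.69, adjusted p = 0.000709). GLB1 rose by 0.30 (SE 0.10, adjusted p = 0.0275), a call that ended without knockdown non-senescent replicate 2 (adjusted p = 0.205) or knockdown senescent replicate 2 (adjusted p = 0.146) and without a filter (adjusted p = 0.0968). The chemokine gene CXCL11 (4.84, SE 0.23) and IDO1, which encodes a tryptophan-degrading enzyme (5.99, SE 0.18), rose; these genes, KIF20A and IFIT2 overlap others, so their own share is uncertain. By edgeR with Benjamini-Hochberg adjustment, 11023 genes changed, 5401 higher and 5622 lower, 3588 of them by at least 2-fold (2463 higher, 1125 lower). The balance turned to 6793 higher and 5254 lower after the GC correction, 5718 and 5107 with RLE size factors and 5554 and 5101 in DESeq2. It did not turn with either other filter or either block. Of the genes called in both irradiation comparisons, 4013 were higher in both and 4559 lower in both, against 1396 and 1422 by chance, and 210 moved in opposite directions. The shared higher and lower genes numbered 5180 and 3987 after the GC correction, 4675 and 3505 with library size alone and 4081 and 4239 in DESeq2.

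Non-senescent knockdown cells had more transcripts of secretory factor genes than scr cells before any irradiation. Of the 45 genes, 31 were higher, 4 lower and 10 did not pass (32 and 5 adjusted over the list alone; median 0.95). CXCL8, a neutrophil chemokine gene, went from 5.90 to 66.7 CPM (3.50, SE 0.16) and IL6 from 0.325 to 4.42 CPM (3.75, SE 0.49), and the adhesion molecule gene ICAM1 rose by 5.21 (SE 0.17). The IL6 baseline rests on 48 and 4 counts in the 2 scr libraries, and with a block for the number in the sample titles the IL6 call ended (3.85, adjusted p = 0.0661). Without scr non-senescent replicate 1 the IL6 change was 6.41. CSF3 went from 1 to 176 counts (ratio 139, 95% counting interval 24.7 to 5540, or 12.2 to 2780 with counts divided by 2, where the lone count stayed at 1). Camera called the list (adjusted p = 5.47e-28), with adjusted p = 0.114 with an estimated correlation and 0.000603 by fry. Of the 18 NF-kB genes, 9 rose and none fell, also adjusted over the list alone (median 0.38; adjusted p = 0.615 with an estimated correlation), with TNFAIP3 at 1.80 (SE 0.11).

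Genes of antioxidant and amino acid metabolism were lower in non-senescent knockdown cells. Of 32 glutathione and NRF2 target genes, 17 fell and 4 rose, also adjusted over the list alone (median -0.29), with CYP4F11 at -1.94 (SE 0.11) and the glutathione peroxidase gene GPX2 at -2.34 (SE 0.12). Of 34 genes of the ATF4 and amino acid response, 16 fell and 4 rose (18 and 5 adjusted over the list alone; median -0.26), with CHAC1, a glutathione-degrading enzyme gene, at -1.58 (SE 0.18). Of 20 transsulfuration and sulfide genes, 11 fell and 1 rose (13 and 1 adjusted over the list alone; median -0.35), with CBS at -0.97 (SE 0.12; the list median was -0.23 without scr non-senescent replicate 1) and MPST, a sulfide-producing sulfurtransferase gene, at -0.79 (SE 0.11). Of 41 replication genes, 21 fell and 2 rose (22 and 3 adjusted over the list alone; median -0.27), and MKI67, a marker of proliferating cells, fell by 0.63 (SE 0.12). Camera called these 4 lists, each with adjusted p = 0.968 with an estimated correlation, and fry called none of them (adjusted p = 0.0502, 0.0646, 0.0502 and 0.0518). The p53 target list was not called (median -0.14, adjusted p = 0.515). CDKN1A did not pass (0.04, SE 0.11, adjusted p = 0.827) but was at 0.39 (adjusted p = 9.77e-05) after the GC correction. MDM2, which overlaps another gene, rose by 0.40 (SE 0.12, adjusted p = 0.0101), a call that ended without scr non-senescent replicate 1 (0.23, adjusted p = 0.226) or knockdown non-senescent replicate 2 (adjusted p = 0.131).

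Smaller falls were seen in non-senescent knockdown cells. Of 58 ribosomal protein genes, 24 fell and 2 rose (25 and 4 adjusted over the list alone; median -0.22), and of 44 respiratory chain genes, 19 fell and 3 rose (22 and 3 adjusted over the list alone; median -0.25), each with adjusted p = 0.968 with an estimated correlation (0.279 and 0.196 by fry). Without scr non-senescent replicate 1 both calls ended (medians -0.07 and -0.12, adjusted p = 0.351 and 0.0556), and without replicate 2 the medians were -0.37 and -0.38. With library size alone they ended too (adjusted p = 0.316 and 0.103), but that scaling moved all genes by 0.16 and left the ribosomal list at -0.27 relative to the median of all genes, as before. The ribosomal call also ended after the GC correction (median -0.04, adjusted p = 0.363). Of 15 heat shock genes, 8 fell (9 adjusted over the list alone; median -0.29, or -0.19 without scr non-senescent replicate 1; adjusted p = 0.968 with an estimated correlation and 0.0502 by fry), and with library size alone that call ended (adjusted p = 0.0583). The log2 fold changes of 13158 protein-coding genes correlated with GC content at rho = -0.56 in this comparison, against -0.34 and -0.19 for irradiation in scr and knockdown cells and -0.25 for knockdown in senescent cells. Genes are not independent replicates for these correlations.

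Several genes were near absent in scr cells and present in knockdown cells, and others the reverse. CAVIN3, a gene of the caveolar coat, rose by 8.53 (SE 0.32) and MAGEA6, a cancer/testis antigen gene, by 8.13 (SE 0.40). Their 6 and 4 counts in scr non-senescent cells were all in replicate 1. Without that library the values were 13.31 and 12.35, so the size of these rises is poorly determined. ARHGEF5 (0 against 758 counts, at least 200-fold higher, or 100-fold with counts divided by 2) and OR2A1-AS1 (0 against 572, at least 151-fold, or 75.5-fold) overlap each other and cannot be assigned separately. Among the largest falls were F5, the coagulation factor V gene (-4.36, SE 0.26), MGAM, an intestinal disaccharidase gene (-4.30, SE 0.19), and USH1C, a scaffold gene of the brush border (-4.10, SE 0.17). ICAM1, GPX2 and MPST also overlap other genes. Of all tested genes 10154 changed, 4936 higher and 5218 lower, 2994 of them by at least 2-fold (2203 higher, 791 lower). The share higher was 48.6% and 66.9% with library size alone. The number called fell to 6402 without scr non-senescent replicate 1 and to 6385 without knockdown non-senescent replicate 2.

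In senescent cells the knockdown again had more secretory factor transcripts. Of the 45 genes, 28 were higher and 5 lower (31 and 5 adjusted over the list alone; median 0.68; adjusted p = 0.232 with an estimated correlation and 0.00181 by fry). CXCL8 went from 95.9 to 540 CPM (2.49, SE 0.15) and IL6 from 8.92 to 58.9 CPM (2.72, SE 0.32; 2.65, adjusted p = 0.0726 with a block for the number in the sample titles). Of 25 cholesterol biosynthesis genes, 18 were higher and 1 lower (19 and 1 adjusted over the list alone; median 0.69; adjusted p = 0.257 with an estimated correlation), with the sterol enzyme gene MSMO1 at 1.48 (SE 0.12). The lysosomal genes NPC1, a cholesterol exporter (1.31, SE 0.11), and CTSB, a protease (1.11, SE 0.11), rose.

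Interferon-stimulated and antigen presentation genes were lower in senescent knockdown than in senescent scr cells. Of 39 interferon-stimulated genes, 24 were lower and 4 higher (26 and 4 adjusted over the list alone; median -0.46; adjusted p = 0.683 with an estimated correlation), with IFITM1, a viral entry inhibitor gene, at -1.41 (SE 0.13) and EPSTI1 moving the other way at 5.07 (SE 0.30). Of 15 MHC class I genes, 13 were lower (14 adjusted over the list alone; median -0.59; adjusted p = 0.517 with an estimated correlation), with HLA-E at -0.76 (SE 0.11). Of 34 ATF4 genes, 22 were lower and 3 higher, also adjusted over the list alone (median -0.54; adjusted p = 0.67 with an estimated correlation), with the stress regulator gene NUPR1 at -2.61 (SE 0.16). Of 18 NF-kB genes, 9 were lower and 1 higher (10 and 2 adjusted over the list alone; median -0.33; adjusted p = 0.683 with an estimated correlation). Among 36 p53 target genes, 13 were lower and 3 higher, also adjusted over the list alone (median -0.14, or -0.16 after the GC correction). Camera called the p53 list (adjusted p = 0.0128), as did fry (adjusted p = 0.0383), but camera with an estimated correlation did not (adjusted p = 0.747). The p53 median was -0.08 without scr senescent replicate 1. Of 15 heat shock genes, 10 were higher and none lower (10 and 1 adjusted over the list alone; median 0.40; adjusted p = 0.683 with an estimated correlation). Of 20 transsulfuration genes, 5 were lower and 1 higher (6 and 1 adjusted over the list alone; median -0.20; adjusted p = 0.836 with an estimated correlation and 0.0801 by fry), with CBS at -1.38 (SE 0.13). The transsulfuration call ended without scr senescent replicate 1 (adjusted p = 0.0851), without knockdown senescent replicate 1 (adjusted p = 0.0683) and after the GC correction (adjusted p = 0.0529).

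CAVIN3 went from 2 to 3055 counts (ratio 1490, 95% counting interval 411 to 12300, or 267 to 58800 with counts divided by 2) and MAGEA6 from 2 to 913 (ratio 444, interval 123 to 3680, or 79.5 to 17600) between senescent scr and senescent knockdown cells, while USH1C (-5.04, SE 0.18) and F5 (-4.43, SE 0.23) were lower. MKI67 was lower by 0.49 (SE 0.12, adjusted p = 0.00274), a call that ended without scr senescent replicate 1 (adjusted p = 0.0652) or knockdown senescent replicate 1 (adjusted p = 0.108), and CDKN1A did not pass (-0.18, SE 0.11, adjusted p = 0.246; -0.22, adjusted p = 0.0454 with library size alone). IFITM1 overlaps IFITM2. By edgeR with Benjamini-Hochberg adjustment, 8010 genes changed, 4315 higher and 3695 lower, 2569 of them by at least 2-fold (1414 higher, 1155 lower). The balance turned to 3538 higher and 4176 lower with library size alone, 4727 and 5200 after the GC correction and 3437 and 4003 with a filter at 1 CPM in 4 libraries. The number fell to 5142 without knockdown senescent replicate 1 and to 5230 without replicate 2. Across both knockdown comparisons, which share no library, 2267 genes were higher in both and 1782 lower in both, against 711 and 644 by chance, and 424 moved in opposite directions (r = 0.44 across genes, which are not independent replicates).

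**Figure D3:**
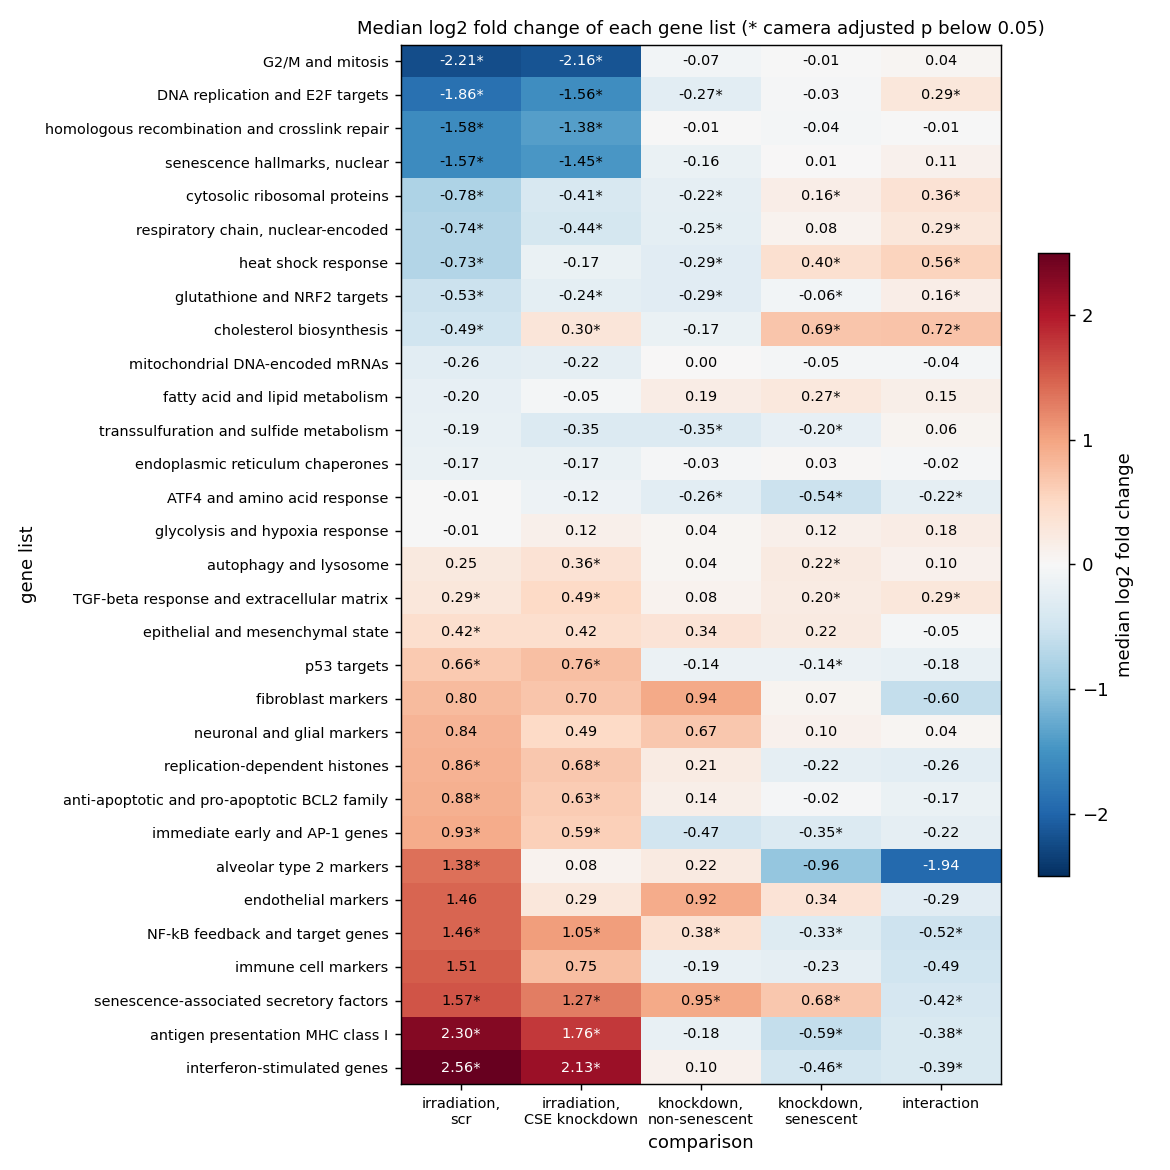
Median log2 fold change (color scale and printed values) of the 31 gene lists (vertical axis) in the 5 comparisons (horizontal axis), with an asterisk where camera's adjusted p is below 0.05. Secretory factor genes have medians of 1.57 and 1.27 after irradiation and of 0.95 and 0.68 in the knockdown comparisons.

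The response to irradiation differed between scr and knockdown cells for 4409 genes by the edgeR interaction test. Of these, 2532 had a higher and 1877 a lower log2 change in knockdown cells. At a difference of at least 2-fold they were 369 and 945. A higher change can be a smaller fall. Regardless of direction, 3676 of the 4409 (83.4%) had a smaller change in knockdown than in scr cells. The cholesterol list had the largest difference toward knockdown: 18 of 25 genes had a higher change and none a lower one (20 and none adjusted over the list alone; median 0.72; adjusted p = 0.15 with an estimated correlation). FDPS, the farnesyl diphosphate synthase gene, went from 123 to 51.3 CPM in scr cells and from 116 to 124 CPM in knockdown cells (difference 1.36, SE 0.15). Heat shock genes followed, 9 of 15 with a higher change (12 adjusted over the list alone; median 0.56; adjusted p = 0.2 with an estimated correlation), with HSPA1A at 1.28 (SE 0.16). In the other direction, 12 of 18 NF-kB genes (15 adjusted over the list alone; median -0.52; adjusted p = 0.15 with an estimated correlation) and 18 of 39 interferon-stimulated genes (21 lower and 1 higher adjusted over the list alone; median -0.39; adjusted p = 0.349 with an estimated correlation) had a smaller rise in knockdown cells. MX2, an antiviral GTPase gene, went from 5.59 to 80.6 CPM in scr and from 14.5 to 78.8 CPM in knockdown cells (-1.40, SE 0.16).

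Of the 45 secretory factor genes, 15 had a lower and 6 a higher change in knockdown cells (16 and 7 adjusted over the list alone; median -0.42, or -0.15 without scr non-senescent replicate 2 and -0.26 without knockdown non-senescent replicate 1; adjusted p = 0.454 with an estimated correlation), with CXCL8 at -1.01 (SE 0.21, adjusted p = 0.00253). For IL6 the difference did not pass (-1.02, SE 0.62, adjusted p = 0.35), but it did without scr non-senescent replicate 1 (-3.72, adjusted p = 3.05e-08) without scr senescent replicate 2 (-1.07, adjusted p = 0.0424) and in limma-voom (-1.82, adjusted p = 0.0443). CTH did not differ detectably in its response (-0.97, SE 0.53, adjusted p = 0.237). FDPS overlaps another gene. The share of the 4409 genes with a higher change was 57.4%, 27.4% with library size alone and 42.4% after the GC correction. The number called fell to 2907 without scr senescent replicate 2, 2669 without knockdown non-senescent replicate 2, and 2725 and 2929 without knockdown senescent replicate 1 and 2.

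Of the 31 lists, camera called 20 and 18 after irradiation of scr and knockdown cells, 9 and 15 for knockdown in non-senescent and senescent cells and 12 for the interaction. With an estimated correlation, 9 lists held in each irradiation comparison: G2/M, replication, recombination, nuclear hallmarks, p53 targets, NF-kB, secretory factors, MHC class I and interferon-stimulated genes. In the other 3 comparisons camera with an estimated correlation called 0 lists (2, 2 and 4 at an unadjusted p under 0.05), while fry, which asks only whether a list moves one way, called 2, 10 and 5. Markers of neuronal and glial, immune, fibroblast and endothelial cells were not called by camera in any comparison. By fry, neuronal and glial (adjusted p = 0.00388), immune (0.0136) and fibroblast markers (0.0368) were higher in irradiated scr cells and neuronal and glial markers (0.00561) in irradiated knockdown cells.

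By position, genes on chromosome 9 stood out in the knockdown comparisons. The 534 protein-coding genes tested there had a median log2 fold change of 0.27 in non-senescent and 0.42 in senescent cells, with 71.9% and 79.4% of them higher, against -0.23 and -0.10 after irradiation of scr and knockdown cells. These were the highest medians of any chromosome in both comparisons. None of 10000 random lists of genes matched for level had a median as high (highest 0.03 and 0.11). These lists were not matched for GC content or position. Other chromosomes also passed their highest medians, such as 4 and 13 in non-senescent (0.13 each) and 2 in senescent cells (0.14). The random lists therefore do not single out chromosome 9. Among 154 windows of 20 Mb, 5 had a median of at least 0.4 in non-senescent cells: 60 to 80 Mb (0.69) and 80 to 100 Mb (0.54) on chromosome 5, and 60 to 80 Mb (0.65), 80 to 100 Mb (0.50) and 100 to 120 Mb (0.51) on chromosome 9. In senescent cells the same windows had medians of 0.61, 0.45, 0.75, 0.43 and 0.58.

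**Figure D4:**
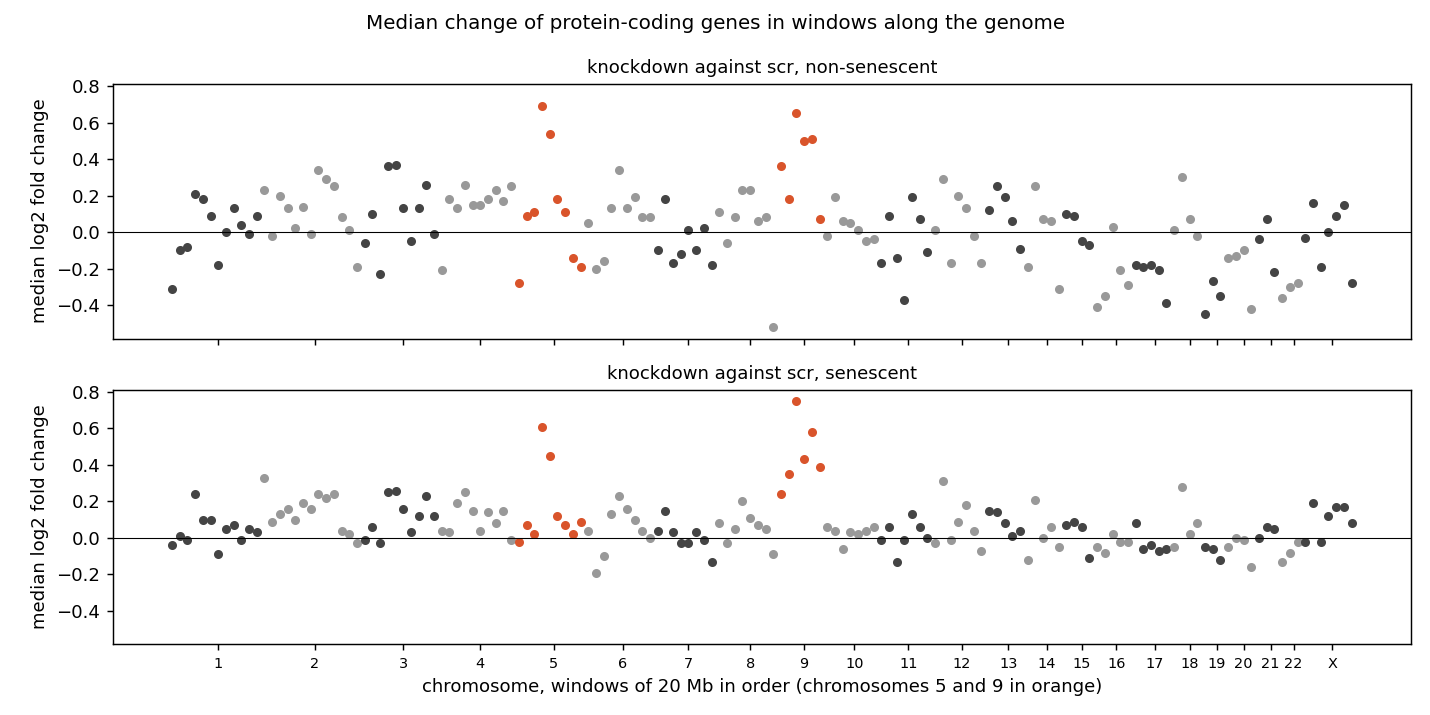
Median log2 fold change of protein-coding genes (vertical axis) in 154 windows of 20 Mb in genome order (horizontal axis), for knockdown against scr in non-senescent (upper) and senescent cells (lower), with chromosomes 5 and 9 in orange. The 5 raised windows lie at 0.50 to 0.69 in non-senescent and 0.43 to 0.75 in senescent cells.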

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

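Among the tests in this part, the marker sum for cells of another type and the test on raised chromosome regions were written beforehand; the GC, scaling, collagen, 5-marker and p53 tests were chosen only after the result was seen. The interaction test picked out 4409 genes whose response to irradiation differed between scr and knockdown cells.

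Sulfur and inflammatory genes differed as follows (difference of log2 changes, knockdown minus scr). MPST differed by 0.70 and CXCL8 by -1.01. TNFAIP3 differed by -1.63, LTB by -3.15 and TNF by -4.43 (95% counting interval -7.68 to -2.55, or -9.97 to -1.81 with counts divided by 2), where scr non-senescent cells had 2 counts of TNF over the group, both in replicate 2 (-7.70 without it). CSF3 differed by -4.26 (interval -9.87 to -2.04, or -8.88 to -1.0) and ARHGEF35-AS1 by -4.88 (interval -10.50 to -2.62, or -9.55 to -1.58), each from 1 count in scr non-senescent cells (CSF3 -6.73 without replicate 1, which held it), and in limma-voom neither passed (adjusted p = 0.0678 and 0.0609). For both genes that lone count was kept at 1 where the other counts were divided by 2. With 0 counts in scr non-senescent cells and 3 counts over the group as floor, the difference was -4.65 or lower for OR2A1-AS1, -3.41 or lower for SAA2 and -3.04 or lower for ARHGEF5 (-3.65, -2.41 and -2.04 with counts divided by 2). The ARHGEF5 call ended in limma-voom (adjusted p = 0.118), without scr non-senescent replicate 1 (0.141) or 2 (0.137), without scr senescent replicate 2 (0.196) and without knockdown senescent replicate 1 (0.0615). RUFY4 differed by -4.39; its call ended without scr non-senescent replicate 1 (adjusted p = 0.157) or 2 (0.16), knockdown non-senescent replicate 2 (-2.28, adjusted p = 0.0837) and knockdown senescent replicate 1 (0.067) or 2 (0.0771).

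The largest differences toward knockdown cells were in PLCXD3 (2.64), OXCT2 (2.61), EBF2 (2.58), DACH1 (2.52), AOX1 (2.44) and OLFML2B (2.42). PLCXD3 (2498 to 704 counts over the group), OXCT2 (110 to 16) and OLFML2B (566 to 120) fell in scr cells. In knockdown cells their counts went from 246 to 347, 1028 to 743 and 182 to 169. EBF2 (130 to 1013), DACH1 (771 to 1840) and AOX1 (634 to 2518) rose in knockdown cells. The EBF2 call ended without scr non-senescent replicate 1 (adjusted p = 0.262) or 2 (0.0521), without knockdown senescent replicate 1 (0.054), with library size alone (0.0665) and with a block for the number in the sample titles (0.95, adjusted p = 0.353). Interferon and antigen presentation genes had smaller rises in knockdown cells: XAF1 (-2.00), MX2 (-1.40), IFIT2 (-1.32), ERAP2 (-1.0), HLA-B (-0.83) and B2M (-0.58). The B2M call ended without knockdown senescent replicate 1 (adjusted p = 0.0537) or 2 (0.0518).

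Cholesterol enzyme genes differed the other way, FDPS by 1.36, MVD by 1.25 and LSS by 1.22, as did the chaperone genes HSPA1A (1.28), FKBP4 (1.07) and HSPA1B (0.98) and the replication genes E2F1 (0.85), POLD1 (0.76) and CDT1 (0.73). After the GC correction CDT1 did not pass (adjusted p = 0.174). Ribosomal genes RPL7A (0.73), RPL13 (0.69) and RPLP1 (0.66) and respiratory genes UQCRC1 (0.68), NDUFB10 (0.67) and ATP5F1D (0.64) fell less in knockdown cells. Without scr non-senescent replicate 1, RPLP1 (adjusted p = 0.0925), NDUFB10 (0.42, adjusted p = 0.0932) and ATP5F1D (0.0833) did not pass. RPLP1 (0.064) and ATP5F1D (0.108) also did not without knockdown senescent replicate 1, nor ATP5F1D without scr senescent replicate 2 (0.0597). With library size alone these 3 did not pass either (adjusted p = 0.0533, 0.0647 and 0.11), nor did ATP5F1D after the GC correction (0.365).

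As lists, the median differences were 0.72 for cholesterol biosynthesis, 0.56 for heat shock, 0.36 for ribosomal proteins, 0.29 for the respiratory chain and 0.29 for replication. After the GC correction they were 0.65, 0.55, 0.22, 0.18 and 0.18. Without scr non-senescent replicate 1 the ribosomal and respiratory medians were 0.18 and 0.16, and without scr senescent replicate 2 the replication median was 0.19. The median differences were -0.52 for NF-kB genes, -0.42 for secretory factors, -0.39 for interferon-stimulated genes and -0.38 for MHC class I. After the GC correction they were -0.92, -0.53, -0.45 and -0.61. Without scr non-senescent replicate 2 the secretory and MHC class I medians were -0.15 and -0.24, and without knockdown non-senescent replicate 1 the secretory median was -0.26. The ATF4 list differed by -0.22 (-0.35 without scr non-senescent replicate 1) and its call ended without scr senescent replicate 1 or knockdown non-senescent replicate 1 (-0.11). After the GC correction it differed by -0.44 (camera adjusted p = 2.45e-09). Glutathione and NRF2 targets differed by 0.16 but by -0.05 with library size alone (adjusted p = 0.255), a scaling that moved all genes by -0.21, and the call ended without scr non-senescent replicate 1 (0.0879). The TGF-beta and matrix list differed by 0.29; its call ended without scr non-senescent replicate 1 (adjusted p = 0.119), scr senescent replicate 2 (0.072), knockdown non-senescent replicate 2 (0.0738) or knockdown senescent replicate 2 (0.0642), with library size alone (0.297) and after the GC correction (0.343). With an estimated correlation none of the 31 lists passed for the interaction (4 at an unadjusted p under 0.05; 5 by fry: cholesterol, NF-kB, heat shock, interferon-stimulated and secretory factor genes).

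Ribosomal protein genes were lower in knockdown than in scr non-senescent libraries (median -0.22; -0.07, adjusted p = 0.351 without scr replicate 1 and -0.37 without scr replicate 2), and a GC trend between libraries may account for it: after the correction the median was -0.04 and the call ended (adjusted p = 0.363). With library size alone it was -0.05 (adjusted p = 0.316), but relative to the median of all genes the list stayed at -0.27, so a scaling error and a fall of the list cannot be told apart by this. In irradiated scr cells the ribosomal median was still -0.41 after the correction (adjusted p = 9.95e-11), against -0.78 without it, which argues against the GC trend as the whole cause there. In senescent cells, from separate libraries, camera called the same list higher in knockdown (median 0.16, 18 rose and none fell, adjusted p = 0.00365). After the GC correction that median was 0.15 (adjusted p = 0.000543). With an estimated correlation adjusted p was 0.913, and the median was 0.07 without scr senescent replicate 2. Whether knockdown itself lowers these genes in non-senescent cells stays open.

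Secretory factor genes were higher in knockdown than in scr non-senescent libraries (median 0.95), and a knockdown effect is a candidate explanation that stays open with a difference between the lines. The GC trend is argued against by a median of 1.09 after the correction (camera adjusted p = 6.35e-44). Since 0 members lay in the raised windows, the median without such members had to be the same 0.95. That argues only against the position of the members themselves as the source. An effect of genes in the raised windows on secretory genes elsewhere was not tested. A p53 response at 0.5 times its size after irradiation is argued against by the p53 list, with a median of -0.14 (0.01 after the correction) and upper quartiles (added after the medians were seen) of 0.14 and 0.19 where 0.33 was needed; a smaller one stays open, since MDM2 rose by 0.40 (0.23, adjusted p = 0.226 without scr non-senescent replicate 1) and CDKN1A was at 0.39 after the correction. For cells of another type, 6 markers summed to 40.5 CPM against 20.1 in scr cells, past the 10 CPM written beforehand as pointing to such cells; COL1A1 held nearly all of it and scr cells express it at 20 CPM, so the sum does not decide, and cells of a type without the other 5 markers and the knockdown cannot be told apart. As a source of the CXCL8 rise, fibroblasts and immune cells are argued against by the other 5 markers (COL1A2, COL3A1, DCN, PTPRC and TYROBP). Their rise was 0.0118 times that of CXCL8 (60.8 CPM) in non-senescent and 0.00375 times in senescent cells. For secretory genes with far smaller rises in CPM, such as IL6 and CSF3, a ratio to CXCL8 cannot decide. These 5 markers did rise, from 0.101 to 0.816 and from 0.466 to 2.13 CPM. COL1A2 rose by 0.0165 and 0.317 times as much as COL1A1, the second of which goes the other way.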

How the results depend on the processing

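Library size without TMM, the GC and span correction, genes overlapping no other gene, and counts divided by 2 were chosen after seeing the data. All others were set beforehand, and every one could be run, with 1 exception. The interaction uses all libraries, so it has no fit with the libraries of a comparison alone. The numbers of called genes stayed within 1.5 times the reported ones with RLE size factors, both other filters, DESeq2, limma-voom, the libraries of a comparison alone, both title-number blocks, library size alone, the GC correction and counts divided by 2. In the order irradiation of scr and knockdown cells, knockdown in non-senescent and senescent cells, and interaction, they were 4549, 3220, 2961, 2345 and 1316 among genes overlapping no other gene, where fewer genes are tested by construction. They were 7024, 3588, 2994, 2569 and 1314 at a fold of at least 2, a stricter rule by construction.

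Camera with an estimated correlation called 9, 9, 0, 0 and 0 lists, and fry called 2 for knockdown in non-senescent cells and 5 for the interaction. These tests make other assumptions about correlation by construction. After the GC and span correction CBS in irradiated scr cells was at 0.51 and CSE1L in non-senescent knockdown cells at -0.21, each with the opposite sign of the reported value; the cause was not tested.

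Leaving out 1 library, with a lone library assumed to vary like the other groups, gave 12211 to 15364 and 7416 to 12003 genes for irradiation of scr and knockdown cells. It gave 6385 to 11055 genes for knockdown in non-senescent cells (6402 without scr non-senescent replicate 1, 6385 without knockdown non-senescent replicate 2) and 5142 to 9178 in senescent cells (5142 and 5230 without knockdown senescent replicate 1 and 2). The interaction had 2669 to 6111 genes: 2907 without scr senescent replicate 2, 2669 without knockdown non-senescent replicate 2, and 2725 and 2929 without knockdown senescent replicate 1 and 2. Genes shared by the knockdown comparisons numbered 2853 to 4632 and by the irradiation comparisons 6025 to 8721. Called lists ranged over 18 to 22, 18 to 19, 9 to 11, 11 to 15 and 10 to 13. Each fit without 1 library has fewer samples by construction.

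A block for the replicate number gave 16160, 12428, 11770, 9800 and 6494 genes. No source says whether these numbers pair the samples. Deviations of replicate 1 from its group mean correlated between groups at -0.081 to 0.327, highest for scr senescent with knockdown non-senescent cells. The log2 difference of replicate 1 from replicate 2 rose with GC content in every group (rho = 0.35 to 0.76). Genes are not independent replicates for these correlations, and a shared replicate effect stays open. With a block for the other title number, IL6 was not called in the knockdown comparisons (adjusted p = 0.0661 and 0.0726), nor were CTH in non-senescent cells (-0.68, adjusted p = 0.206), GLB1 in irradiated scr cells (0.18, adjusted p = 0.129) or EBF2 in the interaction (0.95, adjusted p = 0.353); the cause was not tested. Depth sets the bound of 3 counts for a group without counts.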

Other observations

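Among the tests in this part, the GC and overlap tests on chromosome 9 were written beforehand; the copy number test and the tests of hepatic and intestinal genes and of cancer/testis antigen genes were chosen only after the result was seen. Genes named here outside the rule for named genes were chosen after their values were seen. The 3 fibrinogen chain genes, which encode a clotting protein made mainly by liver, responded to irradiation in opposite directions in the 2 lines. FGA, FGB and FGG rose in scr cells by 0.88 (SE 0.20), 1.06 (SE 0.36) and 1.18 (SE 0.33) and fell in knockdown cells (-1.81, SE 0.21; -2.29, SE 0.39; -1.36, SE 0.36). The interaction passed for each (adjusted p = 4.96e-07, 0.000112 and 0.00073).

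HNF4A, a transcription factor gene of liver and gut epithelium, was lower in both knockdown comparisons (-2.16 in non-senescent and -2.08 in senescent cells). MUC13, a membrane mucin gene (-1.94 and -3.19), and SERPINA1, the alpha-1 antitrypsin gene (-2.79 and -1.79), moved with it, while FOXA1 (1.08 and 1.71) and APOE (1.43 and 1.91) were higher. A list of 38 hepatic and intestinal genes, drawn up from general knowledge after the largest changes were seen and holding none of F5, USH1C and MGAM, had 16 lower and 6 higher members in non-senescent and 20 lower and 3 higher in senescent cells (medians -0.41 and -1.17). Besides FOXA1 and APOE, the members called higher in non-senescent cells were TF (5.32, SE 0.99), FGB (1.12), F2 (0.72) and VIL1 (0.67). The list does hold HNF4A, MUC13, SERPINA1, FOXA1, APOE and the fibrinogen chain genes, so these are not evidence separate from the list. The list was not tested without them. Camera called it in both, the larger adjusted p being 1.23e-08, and with an estimated correlation adjusted p was 0.0209 and 0.00782 (unadjusted 0.0104 and 0.00391). Adjustment covered only this list and the cancer/testis antigen list below. The lists set beforehand were adjusted over all 31, so adjusted values cannot be compared between them and this list. Unadjusted, camera with an estimated correlation put 2 of those 31 under 0.05 in each knockdown comparison. Lower expression of most called members of this list in knockdown cells may be a difference between the lines or an effect of knockdown.

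MAGEA3, a cancer/testis antigen gene, was higher by 6.16 (SE 0.60) and 6.93 (SE 0.67), beside MAGEA6. Higher expression of such genes as a class is a hypothesis that 12 genes left undecided: camera did not call them (the larger adjusted p was 0.233), while fry did (adjusted p = 0.00469 and 0.0047) but not without MAGEA3 (0.0895 and 0.0934), a relative of the MAGEA6 gene that prompted the list. The absence of a camera call was first read as evidence against the class, and the fry result was weighed afterwards. Of the 12, 2 were higher and 2 lower in non-senescent cells and 1 was higher in senescent cells. The 2 lower genes were XAGE1A (-0.59) and XAGE1B (-0.60). Their values were also nearly the same in senescent cells (-0.04 and -0.05), so they may not be separate measurements.

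The raised windows on chromosomes 5 and 9 may reflect a copy number difference between the scr and knockdown lines. They were picked on values without the GC correction and do not mark the ends of a raised region. After the correction, chromosome 9 was also raised at 20 to 40 Mb (0.28 in non-senescent and 0.30 in senescent cells) and 120 to 140 Mb (0.34 and 0.38). The 309 genes in the 5 windows, chosen in non-senescent libraries, had a median of 0.56 in the separate senescent libraries, 87.4% of them higher, against 0.02 for other genes, and of 0.07 and 0.05 after irradiation. The GC trend is argued against by chromosome 9 medians of 0.34 and 0.36 after the correction, and reads shared between overlapping genes by 0.35 and 0.41 over genes that overlap no other. Expression alone does not measure copy number, and whether such a difference arose with the knockdown or by selection of cells stays open. This reading assumes separate scr and knockdown lines, which no source used here states.

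The 294 olfactory receptor genes summed to 0.747 and 0.694 CPM in scr non-senescent, 1.63 and 3.06 in scr senescent, 0.753 and 1.52 in knockdown non-senescent and 1.40 and 1.39 in knockdown senescent libraries.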
